A study of Mus musculus with 32 samples.

How the data were processed

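The series holds 32 CUT&RUN libraries of sorted mouse tumour cells in 16 groups of 2, from B16-F10 (B16) and its resistant derivative Res499, each with STAT1 intact (WT) or knocked out (KO). The antibodies were against H3K27ac, H3K4me1 and H3K4me3, with an IgG control. The 8 IgG libraries were not analysed here, so no background of the antibody was set beside the values. The 24 libraries of the 3 marks, in 4 groups of 2 per mark, entered the comparisons. Groups and replicate numbers were taken from the sample labels.

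Per the submitters' processing notes, reads were trimmed with cutadapt (version 1.18) and aligned with Bowtie2 (version 2.3.4.1) on GRCm38, and MACS2 and DESeq2 were used, with no versions given. The deposited tables give, for each mark, variance-stabilised values on a log2 scale, which the authors made from insertion counts over a set of consensus regions (58687 for H3K27ac, 123867 for H3K4me1 and 66082 for H3K4me3), divided by a size factor per library. That the counts were of insertions over consensus regions and that WT libraries were pooled comes from the names of the deposited tables. How the regions were called and merged is not given in the sources used here, so regions marked only in KO cells may be missing. Of the H3K4me3 regions, none had a count of 0 in either Res499 WT library, against 12 and 9 in the B16 WT libraries, 26 and 49 in B16 KO and 7 and 6 in Res499 KO. The transformation shrinks differences between low counts towards 0, most of all for H3K4me1.

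The transformation was inverted with its closed form, taking the lowest value of each table as a count of 0, and 100% of the values came within 0.1 of a whole number. The lowest and highest recovered totals of each mark are given in the report. They were used to describe depth, to give counts divided by the recovered size factors (normalised counts) and for the added alternatives. Totals count PCR copies, and precision rests on the spread between the 2 libraries of a group. A normalised count of a gene is the sum over its linked regions, and folds are ratios of group means of these counts. A log2 difference of a gene is the mean of the differences of its regions on the deposited scale, so it is smaller than the log2 of the fold.

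Regions were tested with limma (version 3.58.1, R version 4.3.3) on the deposited values. The fit had 4 group means per mark over its 8 libraries, which leaves 4 residual degrees of freedom, and moderated the spread with a mean-variance trend. Adjusted p-values are Benjamini-Hochberg over all regions of a mark, or over all genes, with a threshold of 0.05. The 5 contrasts were Res499 WT against B16 WT, Res499 KO against Res499 WT, B16 KO against B16 WT, Res499 KO against B16 KO, and the difference of the knockout differences between the lines. Prior degrees of freedom were 65.69, 92.27 and 15.2 for regions of H3K27ac, H3K4me1 and H3K4me3 and 9.638 and 8.174 for genes of H3K27ac and H3K4me1. For H3K4me3 genes the prior was infinite, so those p-values take no account of a gene's own spread, and a robust moderation (statmod version 1.5.0) was added as an alternative.

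Regions were linked to 21887 protein-coding genes of a RefSeq table of GRCm38.p6, the build of the data. The design named windows around transcription start sites. The table carries no strand, so windows were set around both annotated gene ends, 2 kb for H3K4me3 and 10 kb for the other marks, a change made before any value was examined. This gave a value to 14039 genes for H3K4me3, 16381 for H3K4me1 and 14590 for H3K27ac. A region can lie in the windows of neighbouring genes, and then both carry its value, as for Psmb8, Psmb9 and Tap1, Irf9, Il18bp, Stat1, Trim30a and Trim30d, and members of the Oas1 family. Values of near-identical family members (Tgtp1 and Tgtp2, the Ifi200 family with Mndal and Ifi203, the Oas1 family) are uncertain, since the handling of reads that map to several places is not given in the sources used here.

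The 16 gene lists were antigen processing and MHC class I, AP-1 and immediate-early genes, cell-cycle genes, cytosolic nucleic-acid sensors, dedifferentiation and mesenchymal genes, housekeeping genes, inhibitory ligands and receptors of T and NK cells, melanocyte lineage genes, MHC class II, myeloid markers, NF-kB response genes, STAT family and interferon receptor signalling, stromal and endothelial markers, T cell markers, and type I and type II interferon genes. Of their 437 symbols, 5 matched no gene of the table. Lists were tested on the genes of a mark with camera (limma) at a preset correlation of 0.01, adjusted over the lists of a mark and contrast, and again with an estimated correlation. Of 240 list tests 63 passed and 12 of those held with an estimated correlation. The gene counts of a list use the limma adjusted p over all genes, and the count adjusted over the list alone stands beside it.

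Genes named in the text follow a rule. For each mark in the first 2 contrasts these are the 4 genes with the largest rise and the 4 with the largest fall in log2 difference past the threshold with no overlap between the libraries of the groups, and 3 and 3 in the other contrasts. Added to these are up to 4 members of each list with the smallest p per mark and contrast, Stat1, and the 2 and 2 single regions with the largest change for the first 2 contrasts. Predicted genes (Gm and Rik names) and olfactory receptor genes were skipped, which does not apply to the name of the gene nearest a region. Genes of the largest changes are all given and list members are examples. The comparisons, tests, lists, naming rule and most alternatives were set before the data were examined.

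Overlap of marks was counted where regions shared at least 1 bp, and the directions of called pairs were compared with a two-sided Fisher's exact test. For reversed marks, which share the Res499 WT libraries, unchanged groups were simulated 20 times. The steps were tested on simulated data with 200 changed regions and 40 changed genes per comparison. In Res499 WT against B16 WT the region test recovered 11.9% (H3K27ac), 38.8% (H3K4me1) and 1.49% (H3K4me3) of 1.5-fold changes, 52.2%, 77.6% and 32.8% of 2-fold changes and 92.4%, 98.5% and 95.5% of 4-fold changes. In B16 KO against B16 WT it recovered 58.2%, 67.2% and 40.3% of 2-fold changes. Of the 40 genes changed 2-fold, 31, 38 and 16 were recovered in the first comparison. Absence of a call for smaller changes is therefore weak evidence, above all for H3K4me3.

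Counts differed within every group by more than sampling noise (chi-square per region from 2.16 to 13.8), so no library was counted as a copy. The correlation across regions between libraries of a group ran from 0.960 to 0.994, lowest for Res499 KO within each mark. Some KO libraries of each mark, but no WT library, correlated more with another group (B16 KO replicate 2 in H3K4me3, 0.991 against 0.989). Alternatives set beforehand were a fit of only the groups compared, quantile normalisation, median centring, no mean-variance trend, leaving out the 25% of regions with the lowest mean, the replicate number as a block, centring each 5 Mb window, leaving out each library, linking regions to the nearest gene end within 50 kb, a threshold of 0.01, an overlap of 50% of the shorter region and a split of shared libraries. Alternatives added after the data were seen were voom on recovered counts, thinning to equal depth, robust moderation and using only the gene end with more H3K4me3. Python (version 3.11.15) with numpy (2.4.6), pandas (2.3.3) and matplotlib (3.10.9) made the tables and plots.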

Results

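Chromatin was profiled by CUT&RUN, an assay in which an antibody guides a nuclease to a histone mark and the DNA released around it is sequenced. The cells were sorted tumour cells of B16-F10, a mouse melanoma line (B16 below), and of Res499, a derivative of B16 that resists immune checkpoint blockade. Each line was used with STAT1 intact (WT) and after knockout of STAT1 (KO), the transcription factor that carries interferon signals to the nucleus. H3K4me3, a mark of active promoters, H3K4me1, a mark of enhancers, and H3K27ac, a mark of active promoters and enhancers, were each measured in 4 groups of 2 libraries, 24 libraries in all. Reads counted over the regions of a mark numbered from 3501365 to 10330849 per library for H3K27ac, from 13103546 to 33473607 for H3K4me1 and from 11500193 to 48803071 for H3K4me3. A Res499 KO library was the shallowest for each mark. The labels name no treatment. They do not say whether replicates came from separate cultures or tumours, so p-values measure at most the spread between these samples, which may be technical. For H3K4me3 genes, p-values and SEs use a spread pooled over genes and not the gene's own. Such p-values can be far smaller than that of the same region. Tested as regions, Phyhipl (Res499 WT against B16 WT) and Mndal (Res499 KO against Res499 WT) had limma adjusted p = 1.27e-09 and 8.32e-05. Differences are on the deposited log2 scale, which shrinks differences between low counts, so folds of normalised counts stand beside them. Changes called largest are ranked by the log2 difference, and their order by fold can differ. Each error is an SD over n = 2 libraries for a count and an SE for a log2 difference.

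The targeted gene was examined first, and its histone marks did not check the knockout, since a mark at a gene end does not read an edit of the coding sequence. Stat1 carried a normalised H3K4me3 count of 2955 in B16 WT, 2460 ± 267 in B16 KO, 2993 ± 56.0 in Res499 WT and 2954 ± 627 in Res499 KO. Its H3K27ac count was 766 ± 51.7, 689 ± 90.6, 704 ± 96.9 and 643 ± 6.14 in the same order. Neither mark differed at Stat1 past the threshold in either line. H3K4me1 at Stat1 was 1.15-fold lower in Res499 KO than in Res499 WT (limma adjusted p = 0.036). This call was lost without any 1 of the libraries except Res499 KO replicate 2. It was also lost with the replicate block (limma adjusted p = 0.0518) and with only the groups compared.

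In B16 cells, the knockout of STAT1 went with a loss of all 3 marks at interferon-stimulated genes. H3K4me3 at Mndal, a member of the interferon-inducible Ifi200 family, fell 36.9-fold from a normalised count of 913 ± 352 to 24.8 ± 14.3 (log2 difference −3.40 ± 0.16, limma adjusted p = 1.75e-95). H3K4me3 was also 22.2-fold lower at Ifi203 of the same family, 13.6-fold at Trim30a, 7.54-fold at Sp100 and 6.15-fold at Oas1g, an oligoadenylate synthetase. It fell from a count of 522 to 32.5 at Tgtp2, an interferon-induced GTPase, and 3.44-fold at Psmb8, a subunit of the immunoproteasome (limma adjusted p from 3.04e-75 to 1.3e-11 for these genes). H3K4me1 fell 4.94-fold at Oas1h (log2 difference −0.58 ± 0.04, adjusted p = 1.25e-05), 21.5-fold at Mndal and 13.8-fold at Tgtp2. H3K27ac fell 5.31-fold at Mndal, from 117 ± 23.9 to 22.1 ± 7.75 (log2 difference −0.57 ± 0.06, adjusted p = 0.00189, or 0.0804 without B16 WT replicate 1). It was 4.43-fold lower at Trim30a (adjusted p = 0.00189, up to 0.0883 without B16 WT replicate 1 or B16 KO replicate 2). It was 3.40-fold lower at Trim30d (0.0174, up to 0.451 without B16 WT replicate 1 or either B16 KO library), a call also lost without the mean-variance trend.

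A few genes gained marks in B16 KO. H3K4me3 rose 2.86-fold at Rasgrp3, a Ras activator, to 1405 ± 47.6 (log2 difference 1.39 ± 0.17, limma adjusted p = 2.49e-13), a call lost under quantile normalisation. Capn6 was 1.90-fold higher (adjusted p = 0.00425, up to 0.96 without B16 WT replicate 1, B16 WT replicate 2 or B16 KO replicate 1) and Ndp 2.43-fold higher (adjusted p = 6.69e-05, up to 0.336 without B16 WT replicate 1 or B16 KO replicate 2). Both were lost without the mean-variance trend, Ndp also under quantile normalisation and Capn6 with median centring (0.0965). H3K4me1 was higher at Pcdh10 (log2 difference 0.15, adjusted p = 0.0242) and 1.33-fold higher at Dbx2 (0.0129). Leaving out any 1 of the B16 libraries ended both calls (adjusted p up to 0.228 and 0.19), as did 5 Mb centring. It was 1.47-fold higher at Serpini2 (adjusted p = 0.00679, up to 0.118 without B16 WT replicate 2 or B16 KO replicate 2).

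Of the type I interferon-stimulated genes, 11 of the 56 measured fell in H3K4me3 in B16 KO (16 adjusted over the list alone), 9 of 58 in H3K4me1 (19 adjusted over the list alone, and 1 rose) and 2 of 56 in H3K27ac (16 adjusted over the list alone). Against all other genes the list was lower in each mark (camera adjusted p = 2.2e-63, 4.72e-12 and 1.94e-18 in the same order), and the 3 calls held with an estimated correlation (adjusted p = 0.0399, 0.0433 and 0.00441). Of the type II interferon-response genes, 8 of 33 fell in H3K4me3, 8 of 36 in H3K4me1 and 1 of 34 in H3K27ac (10, 14 and 13 adjusted over the list alone). Their camera adjusted p was 2.53e-42, 5.42e-15 and 5.19e-22, and all 3 calls held with an estimated correlation. Among cytosolic nucleic-acid sensors, 7 of 23 fell in H3K4me3 (8 adjusted over the list alone). The mean of that list was −0.49 and its median 0.01, so the list was lower through part of its members (camera adjusted p = 6.1e-54, held). Its H3K27ac call held with that correlation (4.81e-07), while its H3K4me1 call did not (2.99e-06, adjusted p = 0.132 with an estimated correlation). Both were lost without the 25% of regions with the lowest values (0.159 and 0.319). H3K4me3 fell at 2 of the 8 MHC class II genes (5 adjusted over the list alone), H2-Ob (6.12-fold) and H2-DMb1 (2.10-fold, adjusted p = 0.00167, up to 0.282 without B16 WT replicate 1, B16 WT replicate 2 or B16 KO replicate 2). Both gene calls were lost without the mean-variance trend, and H2-DMb1 also under quantile normalisation. The list's camera adjusted p was 3.84e-17 (adjusted p = 0.0557 with an estimated correlation). The antigen processing list was lower in H3K4me3 (3 of 21 fell, 4 adjusted over the list alone; camera adjusted p = 8.77e-09), in H3K27ac (0.000872) and in H3K4me1 (0.0139, up to 0.116 without B16 WT replicate 1 or B16 KO replicate 2). None of these calls held with an estimated correlation (adjusted p = 0.427, 0.111 and 0.448), and those in H3K27ac and H3K4me1 were also lost without the regions with the lowest values (0.217 and 0.0554). The H3K4me1 call was lost under quantile normalisation too (0.0906). Inhibitory ligands and receptors of T and NK cells were lower in H3K27ac (median −0.04, camera adjusted p = 0.000126, adjusted p = 0.111 with an estimated correlation). They were also lower in H3K4me3 (median −0.06, camera adjusted p = 0.0162, adjusted p = 0.584 with an estimated correlation), a call lost without B16 WT replicate 1 (0.109) or B16 KO replicate 2 (0.1).

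Over single regions, B16 KO differed from B16 WT at 270 of 66082 H3K4me3 regions (14 higher, 256 lower), 339 of 123867 H3K4me1 regions (139 higher, 200 lower) and 30 of 58687 H3K27ac regions (4 higher, 26 lower). Quantile normalisation gave 99 higher and 232 lower H3K4me1 regions, and centring on 5 Mb windows 0 higher and 23 lower H3K27ac regions. Without B16 WT replicate 1 or 2 there were 94 or 158 H3K4me3 regions, 49 or 88 H3K4me1 regions and 6 or 14 H3K27ac regions. Without B16 KO replicate 2 there were 116, 92 and 10 regions of these marks, and without B16 KO replicate 1 there were 135 H3K4me1 and 13 H3K27ac regions. Leaving out Res499 KO replicate 1 or 2, which enter only the estimate of the spread, raised the counts to 695 or 705, to 1047 or 1042 and to 73 in either case.

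**Figure D1:**
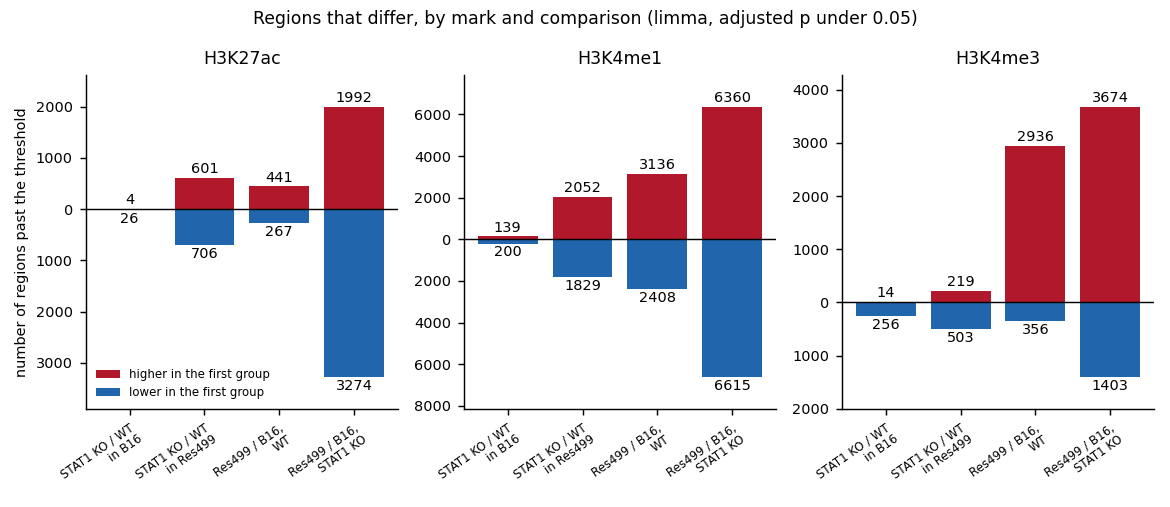
Bars give the number of regions called higher (above 0) or lower (below 0) by limma at an adjusted p under 0.05, for each mark and each of 4 comparisons. H3K4me3 regions were mostly lower in B16 KO than in B16 WT (256 of 270) and mostly higher in Res499 WT than in B16 WT (2936 of 3292).

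In Res499 cells, STAT1 knockout also went with loss of marks at interferon-stimulated genes, and with a loss of H3K4me3 at most MHC class II genes. H3K4me3 at Mndal fell 9.95-fold, from 842 ± 93.3 to 84.6 ± 83.6 (log2 difference −2.67 ± 0.16, limma adjusted p = 4.48e-58). Ifi203 was 7.48-fold lower, Trim30a 5.49-fold, Oas1g 4.69-fold and Gbp9, an interferon-induced GTPase, 5.92-fold lower (limma adjusted p from 7.58e-43 to 6.12e-20). In the pathway that presents antigen to CD4 T cells, H3K4me3 fell at 6 of the 8 measured MHC class II genes. Among them H2-Ob fell 4.61-fold, from 232 ± 3.22 to 50.4 ± 21.4 (adjusted p = 2.5e-14), H2-DMb1 2.84-fold (1.11e-09) and H2-Ab1 2.12-fold (8.52e-05, or 0.191 without Res499 WT replicate 2; also lost without the mean-variance trend). H3K4me1 fell 8.59-fold at Mndal, 2.64-fold at Oas1h, 7.67-fold at Ifi203 (limma adjusted p from 2.75e-05 to 0.000443) and 3.13-fold at Tgtp2 (0.00728, up to 0.0686 without either Res499 WT library). The largest H3K27ac falls by log2 difference were at Clec2d, an NK receptor ligand (1.94-fold), Tgtp2 (3.81-fold), Jun, a subunit of AP-1 (1.64-fold), and Ddx60 (2.02-fold), with adjusted p from 0.00372 to 0.0342. The calls at Clec2d and Tgtp2 were lost without Res499 WT replicate 2 (adjusted p = 0.14 and 0.07). That at Ddx60 was lost without either Res499 WT library (up to 0.0769) and that at Jun without any 1 library except Res499 KO replicate 2 (up to 0.196) and after 5 Mb centring.

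Genes that gained marks in Res499 KO included Hoxa5, a homeobox gene, where H3K4me3 rose 3.20-fold from 215 ± 15.4 to 688 ± 160 (log2 difference 1.36 ± 0.16, limma adjusted p = 9.6e-14). Gpc5, a glypican, was 2.55-fold higher, Mlh3, a mismatch repair gene, 2.74-fold and Cd14, a receptor for bacterial lipopolysaccharide, 2.55-fold higher (limma adjusted p from 1.51e-09 to 8.93e-07), and the Gpc5 call was lost without the mean-variance trend. H3K4me1 rose 2.56-fold at Adgrb3 and 1.78-fold at Dync1i1 (adjusted p = 0.000671 and 0.000155), 1.35-fold at Cyp2d11 (0.00729, or 0.0808 without Res499 WT replicate 1) and 1.36-fold at Ldhd (0.00996, up to 0.0839 without either Res499 WT library). H3K27ac was higher at Speer4d (2.41-fold), Plec (2.91-fold), Tafa5 (2.60-fold) and Neurod6 (1.57-fold), with limma adjusted p from 0.0179 to 0.0473. Tafa5 lost its call without either Res499 WT library (up to 0.191) and Speer4d without these or Res499 KO replicate 1 (up to 0.14). Plec lost it without these 3 or either B16 KO library (up to 0.196), and Neurod6 without any 1 library except Res499 KO replicate 1 (up to 0.24). Centring 5 Mb windows also ended the H3K27ac calls at Speer4d, Plec and Neurod6. Chromosomes 6 and 15 lay higher as a whole in Res499 KO (H3K27ac median of 0.24 for each). Gains on them, as at Tafa5 on chromosome 15, may in part follow the chromosome. No H3K27ac gene named for this comparison kept its call when only the 4 libraries compared were fitted (adjusted p from 0.0604 to 0.127).

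Of the type I interferon-stimulated genes, 9 of 56 fell in H3K4me3 in Res499 KO, 15 of 58 in H3K4me1 and 8 of 56 in H3K27ac (13, 23 and 25 adjusted over the list alone, where 1 also rose in each of H3K4me1 and H3K27ac). The camera adjusted p was 2.43e-30, 4.21e-09 and 9.13e-05, and with an estimated correlation the adjusted p was 0.0858, 0.0595 and 0.0806, so none held. Of the type II interferon-response genes, 6 of 33 fell in H3K4me3, 10 of 36 in H3K4me1 and 10 of 34 in H3K27ac (9, 13 and 16 adjusted over the list alone, where 1 rose in H3K27ac; camera adjusted p = 1.05e-26, 3.11e-13 and 9.13e-05). With an estimated correlation the H3K4me3 call held (adjusted p = 0.044) and the others did not (adjusted p = 0.0595 and 0.0904). Sensors (7 of 23 fell in H3K4me3, 8 adjusted over the list alone) and MHC class II genes (6 of 8, the same count adjusted over the list alone) were lower in H3K4me3 with camera adjusted p = 2.49e-23 and 2.13e-31, and both calls held. The list of T cell markers was also lower in H3K4me3 (camera adjusted p = 5.75e-05, held). Only Cd3d fell among its 10 measured members, with 2 adjusted over the list alone, and the list's call was lost without Res499 KO replicate 1 (adjusted p = 0.149) and under quantile normalisation (0.154). The call at Cd3d (2.72-fold lower, adjusted p = 0.0027) was lost without Res499 WT replicate 1 or Res499 KO replicate 2 (up to 0.756), and under quantile normalisation, 5 Mb centring, voom and a fit without the trend. In H3K4me1 the sensors (camera adjusted p = 3.25e-06), the antigen processing list (2.43e-05) and MHC class II (0.000651) were lower, and none held with an estimated correlation (adjusted p = 0.133, 0.236 and 0.245). The sensors were also lower in H3K27ac (0.00182, adjusted p = 0.0904 with an estimated correlation) and antigen processing in H3K4me3 (0.000782, adjusted p = 0.844 with an estimated correlation; 0.0859 without Res499 KO replicate 2). Without the 25% of regions with the lowest values the sensors in H3K27ac (0.556) and MHC class II in H3K4me1 (0.727) lost their calls.

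By coordinate on GRCm38, the largest H3K4me3 falls in Res499 KO lay on chromosome 1 from 173877193 to 173880728 at an end of Mndal (log2 difference −2.67 ± 0.29, limma adjusted p = 8.32e-05) and on chromosome 14 from 100025586 to 100027332 inside Klf12 (−2.40 ± 0.25, 9.46-fold lower). H3K27ac fell 4.54-fold over the latter site (100026191 to 100027296) and 2.52-fold on chromosome 11 from 49086397 to 49088877 within a gene, 8110 bp from an end of Ifi47. The largest H3K4me1 falls were intergenic on chromosome 6, from 129212993 to 129217219 near Clec2d (1056 ± 78.3 to 201 ± 8.04) and from 129229643 to 129233113 near Cd69 (4.15-fold, to 139 ± 45.3). The largest rises were on chromosome 12 from 5119327 to 5120666 inside Klhl29 (5.56-fold) and on chromosome 5 from 41702579 to 41704478 inside a gene 3715 bp from an end of Rab28 (4.34-fold) for H3K4me3. For H3K4me1 they were on chromosome 11 from 34110735 to 34114291 near Lcp2 (2.23-fold) and on chromosome 15 from 87711737 to 87718413 inside Tafa5 (2.25-fold). For H3K27ac they were intergenic, on chromosome 3 from 29890724 to 29891829 near Mecom (2.06-fold) and on chromosome 6 from 4170335 to 4172319 near Bet1 (1.87-fold).

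Res499 KO differed from Res499 WT at 722 H3K4me3 regions (219 higher, 503 lower), 3881 H3K4me1 regions (2052 higher, 1829 lower) and 1307 H3K27ac regions (601 higher, 706 lower). Of the lower H3K27ac regions 61.0% lay within 2 kb of a gene end, against 20.3% of all regions and 5.32% of the higher ones. Quantile normalisation gave 712 higher and 1001 lower H3K4me3 regions. For H3K27ac it turned the balance to 822 higher and 583 lower, while median centring gave 390 and 979 and 5 Mb centring 206 and 386. For H3K4me1, quantile normalisation turned the balance to 1535 higher and 1818 lower and 5 Mb centring to 1233 and 1338. Without Res499 WT replicate 1 or 2 there were 87 or 79 H3K4me3 regions, 1153 or 635 H3K4me1 regions and 222 or 30 H3K27ac regions. Without Res499 KO replicate 1 or 2 there were 1739 or 6700 H3K4me3 and 633 or 3606 H3K27ac regions, and without B16 WT replicate 1 or 2, which enter only the spread, 722 or 716 H3K27ac regions.

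**Figure D2:**
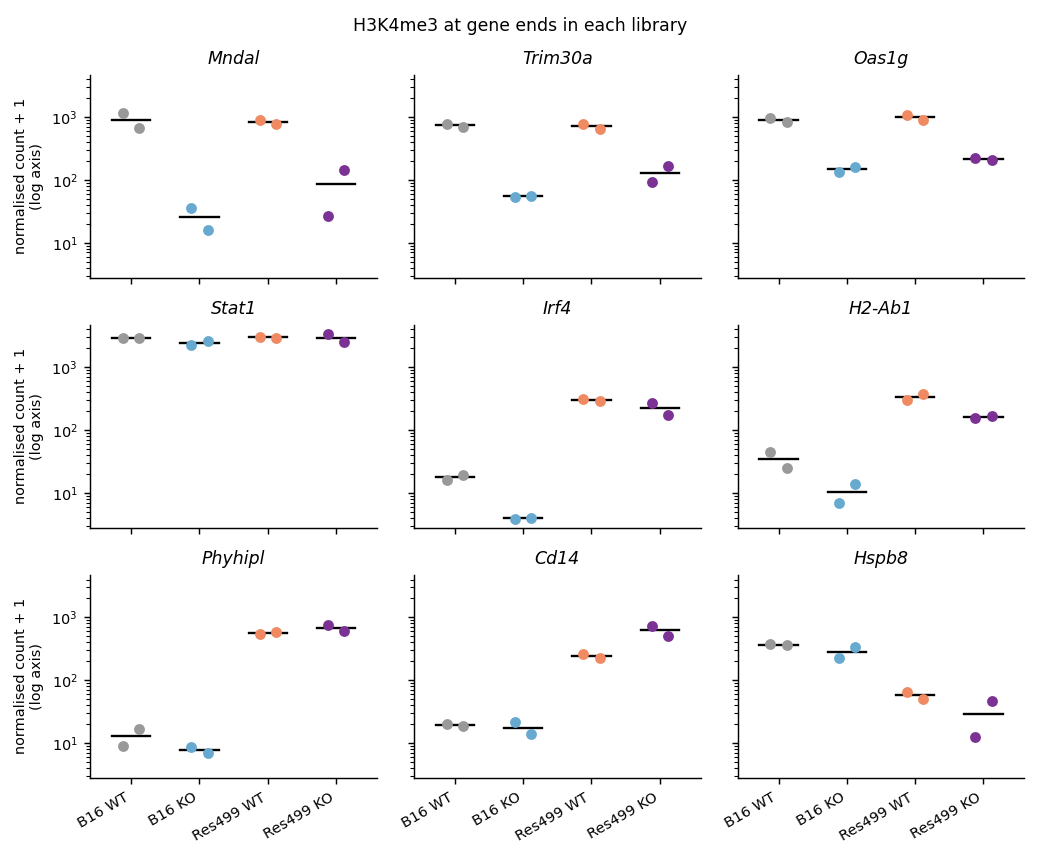
Each point is the normalised H3K4me3 count plus 1 of a library at a gene (log axis), with 2 libraries per group and a bar at the group mean. Mndal lay near 900 in both WT groups and below 100 on average in both KO groups, whereas Phyhipl lay at 563 in Res499 WT and 675 in Res499 KO and near the bottom of the axis in B16.

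The resistant line was then compared with its parent, both with STAT1, to find what distinguishes their chromatin. H3K4me3 was higher in Res499 WT at genes nearly without the mark in B16 WT. Phyhipl rose 47.2-fold from 11.9 ± 5.56 to 563 ± 24.8 (log2 difference 3.12 ± 0.16, limma adjusted p = 9.87e-84). Gsx1, a homeobox gene, rose 41.0-fold from 11.4 ± 5.38 to 467 ± 54.2 (1.29e-72). Dchs2, a protocadherin, went from a count of 0.800 ± 1.13 to 258 ± 29.1 and Bicc1 from 0.345 ± 0.488 to 242 ± 9.85, both too low in B16 WT for a fold. Irf4, a melanocyte and lymphocyte transcription factor, was 18.0-fold higher (1.76e-41) and Zeb1, a driver of mesenchymal states, 4.47-fold higher (4.51e-14). The largest falls were at Hspb8, a small heat shock protein (6.49-fold, from 369 ± 2.95 to 56.8 ± 11.6, adjusted p = 1.64e-27), Dlk1 (3.51-fold), Rasgrp3 (2.89-fold) and Mlh3 (2.62-fold). H3K4me1 rose 3.23-fold at Car2, a carbonic anhydrase, 5.38-fold at Hey1, a Notch target, 2.55-fold at Pou3f2, a neural and melanoma transcription factor, and 1.48-fold at Ackr3. It fell 3.54-fold at Tafa5, 2.23-fold at Pcdh15, 2.72-fold at St8sia2 and 1.48-fold at Tlr9 (limma adjusted p from 3.39e-06 to 0.00193 for these 8). The Irf4, Zeb1, Phyhipl and Tafa5 calls held without any 1 library.

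H3K27ac was higher at Hook1 (3.58-fold, to 116 ± 3.86, limma adjusted p = 0.00133), Pabpc4l (2.73-fold, 0.00257), Nhsl1 (2.24-fold, 0.00275) and Adal (1.88-fold, 0.00399). It was lower at Nrp2, a semaphorin and VEGF receptor (log2 difference −0.49, 0.0134), Tafa5 (3.10-fold, 0.00257), Hspb8 (7.16-fold, 0.0338) and Pcdh15 (2.52-fold, 0.0322). The Hook1 call alone held without any 1 library. Those at Pabpc4l, Nhsl1 and Tafa5 were lost without B16 WT replicate 1 or Res499 WT replicate 2 (adjusted p up to 0.0708). Those at Adal and Nrp2 were lost without these or B16 WT replicate 2 (up to 0.102 and 0.198), that at Pcdh15 without any 1 of the libraries compared (up to 0.273), and that at Hspb8 without any 1 of these or of the B16 KO libraries (up to 0.281). The calls at Hspb8 and Pcdh15 were also lost after 5 Mb centring and without the mean-variance trend, and that at Hspb8 with the replicate block (0.0535).

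H3K4me3 and H3K4me1 were higher at several MHC class II genes in Res499 WT. All 8 measured MHC class II genes had a positive H3K4me3 difference and 5 rose (5 adjusted over the list alone). H2-Ab1 went from 33.7 ± 14.5 to 341 ± 50.9 (10.1-fold, limma adjusted p = 4.13e-35) and H2-Ob from 47.6 ± 3.93 to 232 ± 3.22 (4.87-fold, 1.39e-15). The list's camera adjusted p was 3.09e-15 (adjusted p = 0.257 with an estimated correlation). In H3K4me1 all 10 measured members were positive and 4 rose (5 adjusted over the list alone; camera adjusted p = 0.00031, adjusted p = 0.584 with an estimated correlation), among them H2-Ab1 (3.16-fold, adjusted p = 0.0298), whose call was lost without any 1 of the libraries compared (up to 0.196). Psmb8 was 2.09-fold higher in H3K4me3. The antigen processing list was higher in H3K4me1 (3 of 22 rose, 6 adjusted over the list alone; camera adjusted p = 0.00031) and H3K4me3 (3 of 21, 4 adjusted over the list alone; 0.0348, up to 0.0684 without B16 WT replicate 2 or Res499 WT replicate 1). Neither call held with an estimated correlation (adjusted p = 0.584 and 0.986), and the H3K4me3 call was lost with median centring (0.104). In H3K27ac neither list passed (camera adjusted p = 0.286 for antigen processing and 0.5 for MHC class II). Leaving out the 25% of regions with the lowest values ended the H3K4me1 calls of MHC class II, antigen processing and the type II list (0.425, 0.425 and 0.249). Type II interferon-response genes were higher in H3K27ac (2 of 34 rose, 6 adjusted over the list alone; camera adjusted p = 0.0123, or 0.123 without B16 WT replicate 2), H3K4me1 (2 of 36, 3 adjusted over the list alone; 0.0394) and H3K4me3 (3 of 33, 3 adjusted over the list alone; 0.0371). With an estimated correlation the adjusted p was 0.323, 0.635 and 0.975. The H3K4me1 and H3K4me3 calls were lost without B16 WT replicate 2 (adjusted p = 0.288 and 0.639) or Res499 WT replicate 1 (0.209 and 0.0701), and that in H3K4me3 with median centring, where the median turned to −0.02 (0.0991). The type I list did not pass in any mark (lowest camera adjusted p = 0.102), although Trim25 rose 2.38-fold in H3K4me3 and Sp100 1.98-fold (limma adjusted p = 2.76e-06, or 0.154 without B16 WT replicate 2; also lost without the mean-variance trend).

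Markers of other cell types moved in the same comparison. The lists of myeloid, T cell, and stromal and endothelial markers were higher in H3K4me3 (2 of 11, 1 of 10 and 3 of 13 rose, and 2, 3 and 4 adjusted over the list alone; camera adjusted p = 0.0348, 0.0348 and 0.0116). None of these calls held with an estimated correlation (adjusted p = 0.284, 0.284 and 0.401) or after quantile normalisation (0.691, 0.191 and 0.347). With median centring the myeloid and T cell calls were lost (0.086 for both), and after 5 Mb centring the myeloid one (0.229), with myeloid medians of −0.08 and −0.14. The myeloid and T cell calls were lost without Res499 WT replicate 1 (adjusted p = 0.0701 and 0.061) and the stromal call without B16 WT replicate 2 (0.0814). Leaving out the 25% of regions with the lowest values turned the myeloid and stromal lists lower than other genes, past the threshold for neither (median −0.22 and −0.21, adjusted p = 0.458 and 0.398). Cd14, a myeloid marker, rose 13.2-fold from 18.6 ± 0.893 (limma adjusted p = 1.65e-32), and Flt1, a VEGF receptor, rose by 1.08 ± 0.16 on the log2 scale (5.23e-10). Stromal markers were lower in H3K27ac (median −0.03, camera adjusted p = 0.0388, adjusted p = 0.323 with an estimated correlation). The call was lost without B16 WT replicate 1 or Res499 WT replicate 2. It was also lost without the 25% of regions with the lowest values (0.466) and with voom (0.0578).

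**Figure D3:**
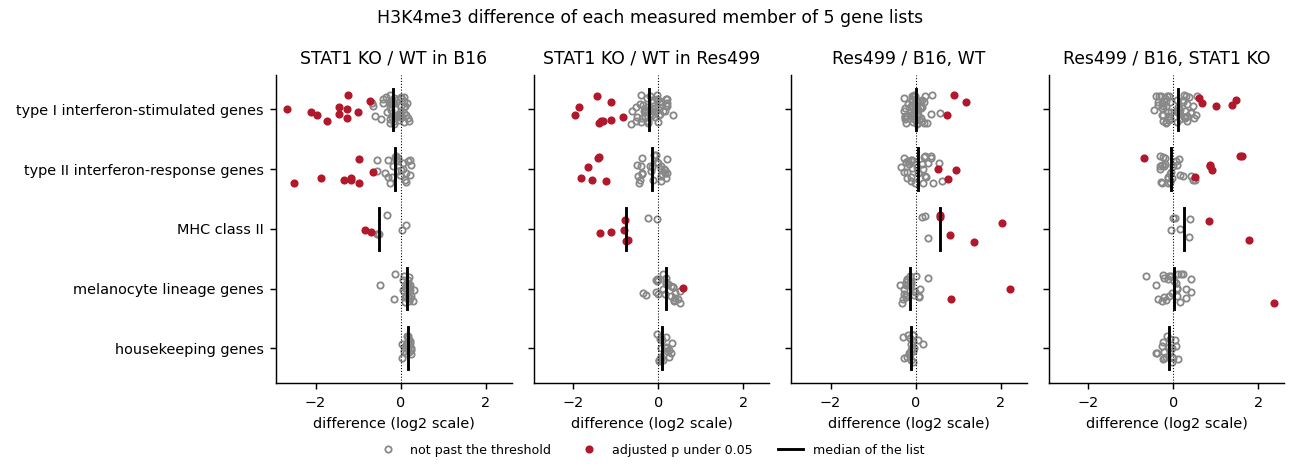
Each point is the H3K4me3 log2 difference of a member of 1 of 5 gene lists in 4 comparisons, red where limma's adjusted p was under 0.05, and black bars mark list medians. MHC class II genes lay above 0 in Res499 WT against B16 WT (median 0.57) and below 0 in Res499 KO against Res499 WT (median −0.76), while housekeeping genes lay close to the all-gene median.

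By coordinate, the largest H3K4me3 rises in Res499 WT were on chromosome 10 from 70598141 to 70600585 at an end of Phyhipl and on chromosome 1 from 11413382 to 11415496 at an end of A830018L16Rik (537 ± 8.48 against 14.3 ± 3.22). The largest falls were on chromosome 5 from 116420653 to 116423164 at an end of Hspb8 and, intergenic, on chromosome 4 from 88948605 to 88954143 near Ifne (4.15-fold lower). H3K27ac was also lower nearby, from 89047101 to 89052372 (log2 difference −0.64), and inside Nrp2 on chromosome 1 from 62711852 to 62722040 (2.06-fold). It was higher on chromosome 1 from 161058865 to 161060106, within a gene near Dars2 (6.66-fold), and on chromosome 3 from 14886088 to 14886662 at an end of Car2 (69.4 ± 10.3 against 0.493 ± 0.698). H3K4me1 rose inside Car2 (14889103 to 14895350, 3.12-fold) and inside Zfhx4 (chromosome 3, 5324023 to 5332209, 1.96-fold). It fell inside Tafa5 (chromosome 15, 87711737 to 87718413, 3.47-fold) and between genes near Chl1 (chromosome 6, 103395285 to 103399069, 2.87-fold).

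Res499 WT differed from B16 WT at 3292 H3K4me3 regions (2936 higher, 356 lower), 5544 H3K4me1 regions (3136 higher, 2408 lower) and 708 H3K27ac regions (441 higher, 267 lower). The H3K4me3 median over all genes was −0.12 in this comparison, 0.12 in B16 KO against B16 WT, 0.08 in Res499 KO against Res499 WT and −0.13 in Res499 KO against B16 KO. Median centring removes these shifts, and the H3K4me3 balance over regions was smaller under quantile normalisation (3435 higher, 1376 lower) and median centring (2622 higher, 844 lower), and median centring turned the H3K4me1 balance to 2628 higher and 2743 lower. Without B16 WT replicate 1 or 2 there were 1574 or 1238 H3K4me3, 1073 or 1305 H3K4me1 and 147 or 188 H3K27ac regions, and without Res499 WT replicate 1 or 2 there were 1273 or 1137, 2008 or 994 and 185 or 125. Leaving out Res499 KO replicate 1 or 2, which enter only the spread, gave 7006 or 7015, 9388 or 9390 and 1754 or 1763.

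Part of the line difference followed long stretches of chromosome. Over 480 windows of 5 Mb, the median differences between Res499 WT and B16 WT correlated between marks (r = 0.832 for H3K27ac and H3K4me1, 0.744 for H3K27ac and H3K4me3, 0.823 for H3K4me1 and H3K4me3), where windows are not independent replicates. Chromosome 15 lay lower in Res499 WT in all 3 marks (median of the log2 ratios −0.18, −0.18 and −0.20 for H3K27ac, H3K4me1 and H3K4me3) and chromosome 13 higher (0.15, 0.14 and 0.08). In Res499 KO against Res499 WT, chromosome 15 lay higher (0.24, 0.18 and 0.23), as did chromosome 6 (0.24, 0.08 and 0.10). Chromosome 6 lay lower in B16 KO against B16 WT (−0.06, −0.09 and −0.05). Centring on these windows left every one of the 24 regions named by coordinate past the threshold.

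**Figure D4:**
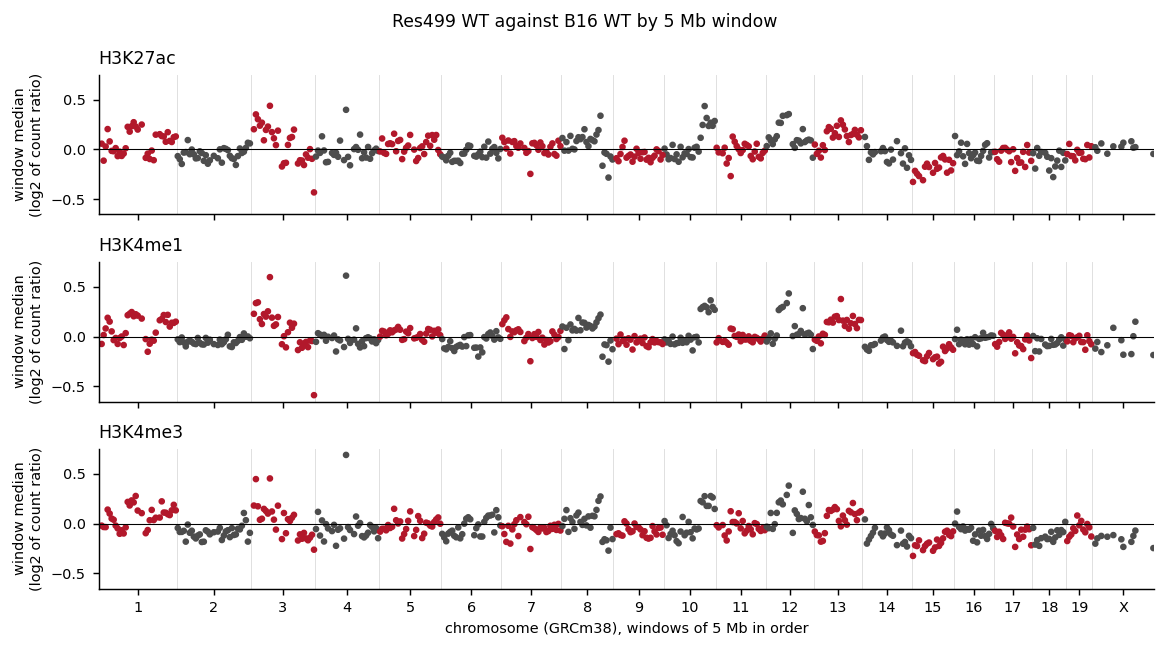
Each point is the median over regions of the log2 ratio of normalised counts plus 1 between Res499 WT and B16 WT in a 5 Mb window, along the chromosomes, for each mark. The 480 windows moved together in the 3 marks, and those of chromosome 15 lay below 0.

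Without STAT1 the lines still differed, and at several interferon-response genes Res499 KO carried more mark than B16 KO. H3K4me3 at Psmb8 was 719 ± 225 in Res499 KO and 141 ± 9.30 in B16 KO (5.08-fold, log2 difference 1.83 ± 0.18, limma adjusted p = 3.59e-22). Tgtp2 was 7.09-fold higher, Sp100 4.91-fold, Gbp5 3.34-fold, Slfn8 3.04-fold and H2-Ab1 17.4-fold (limma adjusted p from 3.19e-27 to 9.12e-08). Phyhipl (99.3-fold, 1.25e-106), Cd14 (37.7-fold, 9.43e-83) and Gsx1 (31.6-fold, 3.88e-73) were the largest H3K4me3 rises by log2 difference, and Irf4 had a count of 221 ± 66.9 against 2.92 in B16 KO. The largest falls were at Rasgrp3 (7.37-fold, 2.35e-46), Hspb8 (9.82-fold) and Ece1, an endothelin-converting enzyme (24.9-fold). H3K4me1 was higher at Neurod6 (1.95-fold), Hey1 (5.22-fold) and Tgtp2 (6.94-fold, adjusted p = 0.0097, or 0.0535 without Res499 KO replicate 2) and lower at Dpt (2.85-fold), Pcdh15 (2.94-fold) and Pf4 (1.91-fold). H3K27ac was higher at Tex9 (4.91-fold), Myh13 (log2 difference 0.49) and Pabpc4l (2.41-fold), with limma adjusted p from 0.000373 to 0.00309, and lower at Ccnd1, cyclin D1 (2.36-fold, 0.000373), Marcks (1.75-fold, 0.00423) and Tyr, tyrosinase (1.59-fold, 0.0155). The Tyr call was lost under quantile normalisation and without Res499 KO replicate 1 or either B16 KO library (up to 0.129).

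The type II list was higher in H3K27ac in Res499 KO than in B16 KO (8 of 34 rose and 3 fell, 13 and 3 adjusted over the list alone; camera adjusted p = 4.32e-06, adjusted p = 0.0547 with an estimated correlation). So was the type I list (5 of 56 rose and 2 fell, 6 and 2 adjusted over the list alone; 0.0003, adjusted p = 0.0547 with an estimated correlation). Parp12 rose 2.07-fold (limma adjusted p = 0.00738, or 0.059 without B16 KO replicate 2) and Il18bp 1.78-fold (0.0148, up to 0.117 without B16 KO replicate 2 or Res499 KO replicate 1). In H3K4me3, the type I list (5 of 56 rose, 7 adjusted over the list alone), the type II list (6 of 33 rose and 1 fell, 8 and 1 adjusted over the list alone), MHC class II (2 of 8, 4 adjusted over the list alone) and antigen processing (3 of 21, 4 adjusted over the list alone) were higher, with camera adjusted p = 0.00524, 0.0152, 5.5e-05 and 0.00524. None of them held with an estimated correlation (adjusted p = 0.932, 0.932, 0.488 and 0.932), and the type II list had a mean of 0.14 and a median of −0.06. Without Res499 KO replicate 2 the type I, type II and MHC class II calls were lost (adjusted p = 0.0867, 0.353 and 0.39), and the type II call also without B16 KO replicate 2 (0.234) and under quantile normalisation (0.12). Myeloid markers and stromal markers were higher in H3K4me3 too (0.00524 for both, adjusted p = 0.473 and 0.488 with an estimated correlation), calls lost without Res499 KO replicate 2 (0.353 and 0.0868), the stromal one also without B16 KO replicate 2 (0.082), and both after quantile normalisation (0.731 and 0.178). The myeloid call was also lost after 5 Mb centring (0.267, median −0.01). Leaving out the 25% of regions with the lowest values turned both lists lower than other genes. The myeloid list was then past the threshold (median −0.51, adjusted p = 0.00775) and the stromal list not (−0.28, 0.669). In H3K27ac, antigen processing (camera adjusted p = 0.0267, up to 0.138 without B16 KO replicate 2 or Res499 KO replicate 2) and T cell markers (0.028, up to 0.153 without B16 KO replicate 1 or either Res499 KO library) were higher, with adjusted p = 0.316 for both with an estimated correlation. Both were lost under quantile normalisation (0.19 and 0.335) and without the 25% of regions with the lowest values (0.578 and 0.628). The T cell call was also lost after 5 Mb centring (0.0868). Housekeeping genes were lower in H3K27ac (2 of 19 fell, 7 adjusted over the list alone; camera adjusted p = 0.01, adjusted p = 0.433 with an estimated correlation), a call lost under quantile normalisation (0.19) and without B16 KO replicate 2 (0.0668) or Res499 KO replicate 2 (0.0823). No list passed in H3K4me1 (lowest camera adjusted p = 0.385).

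Res499 KO and B16 KO differed at 5077 H3K4me3 regions (3674 higher, 1403 lower), 12975 H3K4me1 regions (6360 higher, 6615 lower) and 5266 H3K27ac regions (1992 higher, 3274 lower). For H3K27ac, quantile normalisation turned the balance to 1421 higher and 1168 lower and median centring gave 1335 and 4193. For H3K4me3 these gave 4539 and 3267, and 3604 and 2421. Without B16 KO replicate 1 or 2 there were 2561 or 1774 H3K27ac and 6890 or 5702 H3K4me1 regions, and without B16 KO replicate 2 there were 2423 H3K4me3 regions. Without Res499 KO replicate 1 there were 3293 H3K27ac and 14405 H3K4me3 regions, and without Res499 KO replicate 2 there were 7922 H3K4me3 regions.

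A KO group can differ from its WT group in more than STAT1. Whether the change with knockout differed between the lines was tested as the difference of the knockout differences. It passed at 60 H3K4me3 regions (52 positive, 8 negative), 871 H3K4me1 regions (440 positive, 431 negative) and 576 H3K27ac regions (199 positive, 377 negative). In H3K4me3 the largest positive genes were Rorb, an orphan nuclear receptor, which went from 28.3 ± 3.85 to 2.90 ± 4.11 in B16 and from 64.3 ± 19.4 to 184 ± 56.5 in Res499 (difference 1.77 ± 0.23, limma adjusted p = 1.68e-10), Lysmd2 (1.57 ± 0.22, 1.56e-08) and Gpc5 (1.49 ± 0.27, 8.77e-05, or 0.0724 without Res499 WT replicate 2). The most negative were Ndp (−1.42 ± 0.22, 6.03e-07), Rasgrp3 (−1.35 ± 0.24, 5.66e-05, up to 0.095 without B16 WT replicate 2 or Res499 WT replicate 1) and Capn6 (−1.20 ± 0.27, 0.00604, up to 0.414 without any 1 of the WT libraries). These H3K4me3 gene calls were all lost without the mean-variance trend, and all but Gpc5 under quantile normalisation. MHC class II genes had a more negative H3K4me3 change in Res499 than in B16 (none of 8 positive, median −0.26; camera adjusted p = 9.38e-05, adjusted p = 0.737 with an estimated correlation), a call lost without B16 KO replicate 1 (0.0536). Without Res499 KO replicate 1 the list lay above the other genes (median −0.13, adjusted p = 0.621). Sensors and the type I list had a more positive one (camera adjusted p = 0.00825 and 0.0231, adjusted p = 0.997 for both with an estimated correlation). Both calls were lost without B16 WT replicate 1 (0.131 and 0.322), B16 KO replicate 2 (0.123 and 0.295) or Res499 KO replicate 2 (0.973 and 0.773), the type I call also without Res499 WT replicate 2 (0.0914). T cell markers had a more negative one (0.00816, adjusted p = 0.424 with an estimated correlation), lost without B16 KO replicate 1 (0.0895) or Res499 KO replicate 1 (0.621). Quantile normalisation ended the H3K4me3 calls of the sensors, the type I list and T cell markers (0.205, 0.493 and 0.346), voom those of MHC class II and the sensors (0.177 and 0.0776), and leaving out the 25% of regions with the lowest values those of the sensors and the type I list (0.872 and 0.439). Melanocyte lineage genes lay higher in H3K4me1 (median 0.03, camera adjusted p = 0.0364) and H3K4me3 (0.11, 0.0447), and stromal markers in H3K27ac (0.03, 0.00562), with no member past the threshold. None of these 3 held with an estimated correlation (adjusted p = 0.881, 0.997 and 0.345). The melanocyte calls were also lost under quantile normalisation (0.0619 and 0.493) and after 5 Mb centring (0.255 and 0.418), and the stromal one without the 25% of regions with the lowest values (0.202) or B16 WT replicate 1 (0.204). The H3K4me1 melanocyte call was lost without replicate 1 of any group (adjusted p from 0.167 to 0.961). That in H3K4me3 was lost without B16 WT replicate 1, either B16 KO library, Res499 WT replicate 2 or Res499 KO replicate 1 (up to 0.481), with the median turned to −0.10 in the last of these, and with median centring (0.105).

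The region counts of this test rested on few libraries and on the scaling. Quantile normalisation gave 146 positive and 58 negative H3K27ac regions and 106 and 37 for H3K4me3, and median centring 126 and 422, and 118 and 56. Without B16 WT replicate 1 or 2 there were 1 or 74 H3K27ac, 163 or 192 H3K4me1 and 16 or 18 H3K4me3 regions. Without Res499 WT replicate 1 or 2 there were 258 or 4, 383 or 193 and 15 or 8. Without B16 KO replicate 1 or 2 there were 174 or 9 H3K27ac and 439 or 310 H3K4me1 regions, and without replicate 2 there were 24 H3K4me3 regions. Without Res499 KO replicate 1 there were 2801 H3K4me1 and 330 H3K4me3 regions, and without replicate 2 there were 2690 H3K27ac and 810 H3K4me3 regions.

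The series title speaks of epigenetic memory tied to interferon, and the design asks how far the marks that set Res499 apart depend on STAT1. In H3K4me3, 236 regions were higher in Res499 WT than in B16 WT and lower in Res499 KO than in Res499 WT, and 32 went the opposite way, 268 in all. In H3K4me1 there were 324 and 338, 662 in all, among them the region inside Tafa5, and in H3K27ac 53 and 33, 86 in all. Centring 5 Mb windows lowered the counts of H3K4me3, H3K4me1 and H3K27ac to 245, 344 and 54. Both calls at the Tafa5 region stayed past the threshold. It lies on chromosome 15, which was lower in Res499 WT and higher in Res499 KO as a whole. Lists drawn independently would share 22.3 H3K4me3, 46.3 H3K4me1 and 5.31 H3K27ac regions of the first kind, and 39.9 H3K4me1 and 2.73 H3K27ac regions of the second. Because both differences use the Res499 WT libraries, unchanged groups were simulated 20 times and gave a mean of 0.05, 0 and 0 reversed regions. With nothing changed hardly any region is called, so these counts do not show what sharing adds among regions that differ, and part of the excess may come from the shared libraries. Splitting the Res499 WT libraries between the differences left 23 or 18 H3K4me3, 66 or 63 H3K4me1 and 10 or 5 H3K27ac regions. The split also takes a library from each difference. Leaving out Res499 WT replicate 2, with the other library still shared, left about as many reversed regions as the split. Leaving out replicate 1 left more in each mark, so these counts do not settle what the sharing adds. The covariance of the differences was −0.0294 in H3K4me3 (−0.0180 simulated), −0.00107 in H3K4me1 (−0.000658 simulated) and −0.00492 in H3K27ac (−0.00263 simulated). Their correlation was −0.384, −0.346 and −0.439, against −0.501, −0.500 and −0.501 simulated. Real differences widen the spread it is divided by, so these values cannot be compared. With the Res499 WT libraries split, none was shared between the differences. The covariance was then −0.0222 or −0.0227 in H3K4me3, −0.000600 or −0.000487 in H3K4me1 and −0.00192 or −0.00324 in H3K27ac. Without Res499 WT replicate 1 the reversed regions numbered 28, 209 and 23. They were also fewer in each mark without either B16 WT library, and more without either Res499 KO library.

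Where regions of different marks overlapped by 1 bp or more and both were called, the marks nearly always moved the same way. In Res499 WT against B16 WT this held for all 217 pairs of H3K27ac and H3K4me1 regions, all 280 of H3K27ac and H3K4me3 and all 877 of H3K4me1 and H3K4me3 (two-sided Fisher's exact test of the directions, exact p = 2.06e-63, 7.58e-65 and 5.4e-144, with regions not independent replicates). In Res499 KO against Res499 WT it held for 99.5% of 193 pairs, all 76 and all 192 (exact p = 6.52e-44, 2.78e-22 and 1.79e-49). In Res499 KO against B16 KO it held for 94.1% of 1098, all 778 and 99.6% of 1678. In B16 KO against B16 WT 13, 18 and 67 pairs were called, of which all, all and 98.5% moved the same way (exact p = 1, 1 and 0.00136), and almost all were lower in both marks. For the difference of the knockout differences there were 28, 6 and 11 pairs (exact p = 4.88e-05, 0.167 and 0.00216), and 5 Mb centring left 8 of the first kind (exact p = 1).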

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

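The 9 tests of explanations given here were chosen after the patterns had been seen, as was thinning to equal depth. The test of the difference between the lines was set beforehand.

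The difference between KO and WT was not the same in Res499 and B16, by a test of the difference itself, at 576 H3K27ac, 871 H3K4me1 and 60 H3K4me3 regions. This test cannot tell STAT1 from other differences between KO and WT cells. Chromosome 6 as a whole lay higher in Res499 KO than in Res499 WT (0.24, 0.08 and 0.10 for H3K27ac, H3K4me1 and H3K4me3). It lay lower in B16 KO than in B16 WT (−0.06, −0.09 and −0.05). Leaving out 1 library gave between 1 (without B16 WT replicate 1) and 2690 (without Res499 KO replicate 2) H3K27ac regions, between 163 (without B16 WT replicate 1) and 2801 (without Res499 KO replicate 1) H3K4me1 regions and between 8 (without Res499 WT replicate 2) and 810 (without Res499 KO replicate 2) H3K4me3 regions. In H3K4me1, Neurod6 differed by 0.29 (limma adjusted p = 0.00697), with counts of 1091 in B16 WT, 726 ± 15.4 in B16 KO, 1167 ± 3.69 in Res499 WT and 1418 ± 47.8 in Res499 KO. Dync1i1 differed by 0.22 (0.0127, or 0.0873 after 5 Mb centring) and Serpini2 by −0.24 (0.00697). The Neurod6 call was lost without Res499 WT replicate 2 (0.0833), the Serpini2 call without B16 WT replicate 2 or Res499 WT replicate 2 (up to 0.0606), and the Dync1i1 call without either B16 WT library, B16 KO replicate 1 or Res499 WT replicate 2 (up to 0.13).

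In H3K4me3 the difference was 1.77 at Rorb, 1.57 at Lysmd2, 1.49 at Gpc5, −1.42 at Ndp, −1.35 at Rasgrp3 and −1.20 at Capn6, with limma adjusted p from 1.68e-10 to 0.00604. It was 1.15 at Cd14, where the mark was at 18.6 ± 0.893 and 16.5 ± 5.38 in B16 WT and KO and reached 622 ± 156 in Res499 KO (adjusted p = 0.000225, or 0.0695 without Res499 WT replicate 2). At Gbp5, an interferon-induced GTPase, it was 1.39 (0.0404), with 1542 ± 185 in B16 WT and 563 in B16 KO against 1773 ± 179 and 1877 ± 452 in Res499 WT and KO. Tgtp2 differed by 0.86 (0.0404). The Gbp5 call was lost without any 1 library except the Res499 KO libraries and the Tgtp2 call without B16 WT replicate 1, B16 KO replicate 2, either Res499 WT library or Res499 KO replicate 2, with an adjusted p of up to 1 for both. Calls at Gpc5, Rasgrp3 and Capn6 were lost without libraries named in the report (adjusted p up to 0.0724, 0.095 and 0.414). Without the mean-variance trend, or with regions linked to the nearest gene end, none of these 9 H3K4me3 genes passed, and after quantile normalisation Gpc5 and Gbp5 did. The replicate block ended the Gbp5 and Tgtp2 calls (limma adjusted p up to 0.194).

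The first pattern is that H3K4me3 was higher far more often than lower in Res499 WT against B16 WT (89.2% of 3292 called regions). Copy number of large segments would lower that share to 50% or below once 5 Mb windows are centred, and it stayed at 88.8%. The log2 difference fell with signal, as a smaller range of values in the Res499 WT libraries would give. Its median was 0.107 in the 16521 regions with the lowest values (689 higher, 26 lower). It was −0.150 in the 16521 with the highest (94 higher, 32 lower). Quantile normalisation, which removes differences in the range of values, left the share at 71.4%. Gains then still outnumbered losses in the regions with the highest values (568 against 165). Scaling could therefore account for a part, and how large a part is not settled. An error confined to the H3K4me3 libraries is argued against by H3K4me1, which was higher at 93.8% of overlaps with the 2120 gains against 52.8% of all overlaps (41.0 percentage points more), and at 4.29% of overlaps with the 303 losses. How the regions were pooled and a difference in biology between the lines also stay open, both untested.

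The second pattern is that type II interferon-response genes carried more H3K27ac in Res499 KO than in B16 KO, a list call that missed the threshold with an estimated correlation (adjusted p = 0.0547). It passed after 5 Mb centring (camera adjusted p = 1.06e-06) and after quantile normalisation (4.66e-05), which argues against copy number and the range of values of the shallow Res499 KO libraries as the whole cause. A share of STAT1-intact cells among the Res499 KO cells cannot be told apart from a difference that outlasts STAT1. The list members would need a median of 8.82% of such cells (quartiles −4.42% and 26.97%, 34 members), against a bound of 35.1% from the H3K27ac retained at 26 STAT1-dependent regions (10th percentile) and of 15.9% to 38.3% from the other marks and libraries. H3K4me3 at Mndal allowed less (25.5 in Res499 KO replicate 1 and 144 in replicate 2, against 842 in Res499 WT), but it is a single gene and list members went both ways, which keeps this open.

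The third pattern is that H3K27ac was lower more often than higher in Res499 KO against B16 KO (37.8% of 5266 called regions were higher). After quantile normalisation 54.9% of called regions were higher, and lower calls among the 25% of regions with the highest values went from 2653 to 625, so a smaller range of values in the Res499 KO libraries may account for the balance. Thinning to equal depth left 35.4% higher and 5 Mb centring 34.9%, which argues against depth and copy number as the whole cause. A loss of H3K27ac at strong regions in the cells would give the same values, and no biological explanation was tested.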

How the results depend on the processing

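Voom on recovered counts, thinning to equal depth, robust moderation and the gene end with more H3K4me3 were chosen after the data were seen, the other alternatives before. H3K27ac had the lowest totals, and in simulated data 11.9% of its 1.5-fold changes were recovered in Res499 WT against B16 WT. Leaving out a Res499 KO library, which enters the spread of every comparison, often raised the counts. The fit takes 1 spread per region for all 4 groups. Libraries of a group correlated least in Res499 KO (r = 0.960, 0.985 and 0.981 for H3K27ac, H3K4me1 and H3K4me3). Calls may therefore be too many where Res499 KO is compared and too few where it is not. Where a library is left out, the lone library of its group is assumed to vary like the other groups. The fit of only the groups compared gives no value for the difference between the lines, which uses all 8 libraries. Cause was not tested for the changes below, except that the threshold of 0.01, the split of shared libraries and the fits with fewer libraries are stricter or smaller by construction.

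Leaving out 1 library at a time, the H3K27ac regions called ran from 125 to 1763 in Res499 WT against B16 WT, from 30 to 3606 in Res499 KO against Res499 WT, from 6 to 73 in B16 KO against B16 WT, from 1774 to 6822 in Res499 KO against B16 KO and from 1 to 2690 for the difference of the knockout differences. The H3K4me1 regions ran from 994 to 9390, from 635 to 5589, from 49 to 1047, from 5702 to 16276 and from 163 to 2801 in the same order. The H3K4me3 regions ran from 1137 to 7015, from 79 to 6700, from 94 to 705, from 2423 to 14405 and from 8 to 810. Regions reversed by STAT1 knockout in Res499 ran from 6 to 289 for H3K27ac, from 68 to 978 for H3K4me1 and from 20 to 1439 for H3K4me3.

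Fitting only the groups compared gave 2178 H3K27ac, 11407 H3K4me1 and 13842 H3K4me3 regions in Res499 WT against B16 WT. It gave 253 H3K27ac and 2119 H3K4me1 regions in Res499 KO against Res499 WT, 53, 787 and 450 regions in B16 KO against B16 WT, and 3110, 8648 and 3191 in Res499 KO against B16 KO. Voom on recovered counts gave 1860 H3K27ac, 8352 H3K4me1 and 4953 H3K4me3 regions in Res499 WT against B16 WT, 824 H3K27ac regions in Res499 KO against Res499 WT, 61 H3K27ac and 728 H3K4me1 regions in B16 KO against B16 WT and 155 H3K4me3 regions for the difference of the knockout differences. Equal depth gave 596 H3K27ac and 1927 H3K4me1 regions in Res499 KO against Res499 WT, 3326 and 8003 in Res499 KO against B16 KO, 291 and 403 for the difference of the knockout differences, and for H3K4me1 3272 in Res499 WT against B16 WT and 223 in B16 KO against B16 WT. Centring 5 Mb windows gave 592 H3K27ac and 2571 H3K4me1 regions in Res499 KO against Res499 WT, 210 and 488 for the difference of the knockout differences and 3423 H3K4me1 regions in Res499 WT against B16 WT.

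Quantile normalisation gave 2589 H3K27ac and 7806 H3K4me3 regions in Res499 KO against B16 KO, 1713 H3K4me3 regions in Res499 KO against Res499 WT, and 204 H3K27ac and 143 H3K4me3 regions for the difference of the knockout differences. Median centring gave 1179 H3K4me3 regions in Res499 KO against Res499 WT and 174 for the difference of the knockout differences. Without the mean-variance trend there were 293 H3K4me3 regions in Res499 KO against Res499 WT, 151 in B16 KO against B16 WT and 5 for the difference of the knockout differences, against 927 for H3K27ac. Leaving out the 25% of regions with the lowest values gave 91 H3K4me3 regions for that difference.

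The labels do not say whether libraries with the same replicate number belong together. Correlations of same-numbered deviations ran from −0.512 to 0.457 in H3K4me3 and from −0.0417 to 0.0908 in the other marks. In H3K4me3 they were positive between WT and KO of a line (0.457 in B16, 0.302 in Res499) and negative between the lines. A pairing within a line is therefore not excluded for that mark, and a block that spans both lines does not model it. With the number as a replicate block there were 2058 H3K27ac and 405 H3K4me3 regions in Res499 KO against Res499 WT, 1319 H3K27ac and 17 H3K4me3 regions for the difference of the knockout differences and 151 H3K27ac and 136 H3K4me3 reversed regions. The block left the other region counts within 1.5 times, 194 of 199 calls of named genes and 239 of 240 list results on their side of the threshold, and 1 list passed newly.

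Reversed regions numbered 18 (H3K27ac), 194 (H3K4me1) and 75 (H3K4me3) at an adjusted p under 0.01. They numbered 54 (H3K27ac) and 344 (H3K4me1) with 5 Mb windows centred. With the Res499 WT libraries split between the differences they numbered 10, 66 and 23, or 5, 63 and 18 in the other order. For the agreement of marks, 5 Mb centring left 8 pairs of H3K27ac and H3K4me1 regions for the difference of the knockout differences (100% the same way, exact p = 1) and 56 pairs of H3K4me1 and H3K4me3 regions in B16 KO against B16 WT (100%, exact p = 1). An overlap of 50% of the shorter region left all 15 results on their side of the threshold.

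With regions linked to the nearest gene end the sign turned at Plec (H3K27ac, −0.043 in Res499 KO against Res499 WT), Ednrb (H3K4me3, −0.059 in Res499 WT against B16 WT) and Irf9 (H3K4me3, 0.0045 in B16 KO against B16 WT), where other regions enter the gene. This link kept 132 of the calls of named genes and lost 57. Leaving out the 25% of regions with the lowest values, which removes weakly marked members, turned H3K4me3 list directions to a median of −0.22 (myeloid) and −0.21 (stromal) in Res499 WT against B16 WT, −0.17 (myeloid) in Res499 KO against Res499 WT, −0.51 (myeloid) and −0.28 (stromal) in Res499 KO against B16 KO and −0.30 (myeloid) for the difference of the knockout differences. In the last 3 comparisons the myeloid list passed as lower (camera adjusted p = 0.0169, 0.00775 and 0.029). For that difference in H3K4me3, the MHC class II list lay above other genes without Res499 KO replicate 1 (median −0.13, the highest of a range that began at −0.50 without Res499 KO replicate 2). The sensors lay below other genes without Res499 KO replicate 2 (median 0.21, the highest of a range that began at −0.11 without Res499 KO replicate 1).

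Of 199 calls of named genes, 193 held with median centring, 177 with quantile normalisation, 166 without the trend, 180 with 5 Mb windows centred, 194 with voom and 197 with robust moderation. Over all fits that left out 1 library, 1358 of 1592 held. The 24 single regions held in every alternative run for them. Of 240 list tests, an estimated correlation lost 51 calls, quantile normalisation lost 18 and gave 2, 5 Mb centring lost 8 and gave 5, and no list changed without the trend. Robust moderation left all 15 region counts within 1.5 times.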

Other observations

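Melanocyte lineage genes lay higher than other genes in Res499 KO against Res499 WT in all 3 marks, though no call held with an estimated correlation and the difference from the change in B16 did not hold either. In H3K4me1, 24 of 29 had a positive difference and Sox10 alone rose (3 adjusted over the list alone; camera adjusted p = 0.000127, adjusted p = 0.259 with an estimated correlation). Sox10, a regulator of the melanocyte lineage, was 1.25-fold higher (limma adjusted p = 0.0307), a call lost under quantile normalisation, after 5 Mb centring, with only the groups compared and without either B16 WT library, either Res499 WT library or Res499 KO replicate 1 (up to 0.229). In H3K27ac the list median was 0.01 against −0.05 for all genes and no member passed (camera adjusted p = 0.00204, adjusted p = 0.15 with an estimated correlation). Stromal and endothelial markers moved the same way in that mark (median 0.01, camera adjusted p = 0.00599, adjusted p = 0.15 with an estimated correlation), with the call lost after 5 Mb centring (0.0849) and without the 25% of regions with the lowest values, where the median turned to −0.01 (0.15). In H3K4me3 the melanocyte list median was 0.19 against 0.08, with Tyr, the pigment enzyme tyrosinase, alone past the threshold (1.54-fold, limma adjusted p = 0.0125). The list's camera adjusted p was 0.0034 (adjusted p = 0.893 with an estimated correlation; 0.475 after quantile normalisation and 0.116 after 5 Mb centring). The Tyr call was lost in every alternative run except the replicate block and the fits without B16 WT replicate 2, B16 KO replicate 2 or Res499 KO replicate 2. Those that lost it include the fits without B16 WT replicate 1, B16 KO replicate 1, either Res499 WT library or Res499 KO replicate 1 (adjusted p up to 1). AP-1 and immediate-early genes were lower in H3K27ac in the same comparison (3 of 20 fell, 5 adjusted over the list alone; camera adjusted p = 0.0445, adjusted p = 0.558 with an estimated correlation). The list's call was lost after quantile normalisation (0.168), with median centring (0.0585), after 5 Mb centring (0.0868) and without either B16 WT library, Res499 WT replicate 2 or either Res499 KO library (up to 0.099). The members were Jun, Atf3 (1.76-fold lower, limma adjusted p = 0.0295) and Klf4 (1.65-fold, 0.0493). Both last calls were lost without any 1 of the WT libraries, and that at Klf4 also without Res499 KO replicate 1 (up to 0.198 and 0.196), and both after 5 Mb centring and with only the groups compared.

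The remaining lists passed in no comparison, with a lowest camera adjusted p of 0.0603 for cell-cycle genes, 0.0848 for STAT family and interferon receptor signalling, 0.293 for dedifferentiation and mesenchymal genes and 0.3 for NF-kB response genes. Single members still changed. H3K4me3 at Irf9, a partner of STAT1 and STAT2, fell 2.68-fold in B16 KO, from 976 ± 150 to 365 ± 54.9 (limma adjusted p = 1.66e-07). H3K4me3 at Irf7 was 1.79-fold higher in Res499 KO than in B16 KO (5.35e-08), and H3K4me1 at Stat2 1.58-fold higher (0.00137). In Res499 WT against B16 WT, H3K4me3 at Ripk3, a kinase of necroptosis, rose from 21.7 ± 2.44 to 75.9 ± 4.23 (7.99e-05) and at Ednrb, an endothelin receptor of melanocytes, from 39.5 ± 4.12 to 119 ± 12.4 (9.48e-06). These calls held without any 1 library, and those at Irf9, Irf7 and Ednrb were lost when regions were linked to the nearest gene end.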
